A study of Apis mellifera with 12 samples.

How the data were processed

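Antennal RNA of 12 honey bee worker libraries, 3 each of newly emerged workers, nurses, foragers and defenders, was sequenced on the DNBSEQ platform per the labels. The authors deposited a table of counts per gene, whole numbers that had not been normalized, and 5 tables of splice events whose values are a fraction, the inclusion level per event and library. Aligner, counting program, genome build, annotation and strand use are not given in the sources used here. The processing, extraction and growth fields of the labels describe a chromatin assay on human cell lines, which cannot apply to bee RNA, and nothing here relies on them. The program that called the splice events is not given either; the column names are of the kind that rMATS writes, and the rule by which events were chosen is not given in the sources used here. Groups were taken from the titles of the samples, and each column was joined to a sample by the group's initials and its number. The numbers after "Rep" in the titles do not run from 1 to 3 in every group, so the number after the group's name was used.

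Library totals ran from 66708813 to 119703929 counts. Of 12319 gene names, 12167 matched a symbol of the NCBI gene list for the Amel_HAv3.1 assembly, which served only for names and gene bounds. After edgeR's filterByExpr on the 4 groups, 11271 genes were tested, which held 99.998% of the counts. Of these, 10802 had a LOC identifier and 373 a symbol. Genes with close paralogs in tandem, such as those of royal jelly proteins, odorant binding proteins and odorant receptors, can share reads, and how such reads were assigned is not given in the sources used here. Correlations between log2 CPM of libraries of 1 group, across genes, were 0.986 to 0.995.

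Counts were scaled with TMM factors and fitted with edgeR 4.0.16 (glmQLFit with robust = TRUE and glmQLFTest, two-sided) in R 4.3.3, with all 12 libraries and the 4 group means in a single model that leaves 8 residual degrees of freedom. Calls are genes with a BH adjusted p under 0.05 within each of the 6 comparisons, and the number with an absolute log2 fold change of at least 1 is given beside them. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. A test of all groups together used the same fit. Levels are CPM with TMM library sizes, and principal components were taken from log2 CPM with a prior count of 2.

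Gene lists were fixed before the data were examined, as were the comparisons, the tests, the alternatives and the rule for naming genes. Of 32 lists, matched by symbol, 25 had a tested member and together held 165 genes. A gene with only a LOC identifier could not enter a list. Each list thus holds only those members of its family that have a matching symbol, and counts below refer to these. No member of the lists of ionotropic receptors, CD36 and SNMP proteins, activity-regulated early genes, glycolysis and trehalose use, fatty acid and hydrocarbon synthesis, mechanosensory and TRP channels, or cilium and intraflagellar transport was found by symbol, case included, in the count table. Matching in any case and by synonym found Kakusei for the early genes and FAR1 for fatty acid and hydrocarbon synthesis. It also placed Tk, a member of the neuropeptide list, among the channels. Tested genes went from 3 to 7 for ribosomal proteins and from 4 to 7 for cytochrome P450s. The other lists cover odorant and gustatory receptors, odorant binding and chemosensory proteins, cytochrome P450s, glutathione S-transferases, cuticle proteins, tanning enzymes, royal jelly proteins, antimicrobial peptides, venom, vitellogenin and hexamerins, and the juvenile hormone and ecdysone pathway. They also cover the clock, neuropeptides, biogenic amines, heat shock, ribosomal and oxidative phosphorylation proteins, and markers of neurons, glia, muscle, photoreceptors, hemocytes and glands. Each list was counted over all genes and adjusted over the list alone. The 12 lists with at least 5 tested members were tested with camera (limma 3.58.1, log2 CPM with a prior count of 2) at a preset correlation of 0.01 and with the correlation estimated per list. With the estimated correlation no list passed in any comparison; the smallest adjusted p was 0.0868.

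Named genes were chosen by rule. The first part took, among called genes with a symbol, at least 5 CPM in the higher group and non-overlapping libraries, the 8 largest log2 fold changes per direction (5 for foragers or defenders against newly emerged workers). The next part took from each list up to 2 members per direction with the smallest adjusted p, or 1 member as a value where none passed. Or2, Or11, Vg, Kr-h1, Per and Mrjp1 were named in every comparison, whatever their result. For splicing, the 3 events per type and comparison with the largest difference in genes with a symbol were taken, at most 12 in all, neural genes first; which genes counted as neural was decided after the tables were read. Splice events were compared by group mean and SD and by whether the 3 libraries of the groups overlapped, with a two-sided exact permutation test for named events (Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3). All 491 events lay within the bounds of their gene in the NCBI list. Positions are 1-based, converted from the start columns of the tables.

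Alternatives were DESeq2 1.42.0, RLE size factors and upper-quartile factors, no low-count filter, a filter of at least 10 CPM in 3 libraries, a fit of only the 2 groups compared, a term for the number that libraries share, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and leaving out each library of the groups compared. Residuals of libraries with 1 number were correlated at 0.222 to 0.423 between defenders and foragers, 0.257 to 0.306 between foragers and newly emerged workers and 0.176 to 0.342 between defenders and newly emerged workers. The correlations ran from -0.15 to 0.261, from -0.184 to 0.293 and from -0.358 to 0.156 for newly emerged workers, foragers and defenders against nurses. The fit with the number term is therefore given beside the counts of the first 3 of these pairs. Fits without the nurse group, other factors in the smaller fits of defenders and foragers, nurse libraries divided between 2 comparisons, leaving out libraries of groups outside a comparison, and list membership matched in any case and by synonym were added after the data were seen. Shared calls were set beside the overlap of independent lists. For the pair with shared nurse libraries they were also set beside 20 simulations of unchanged groups that share nurse libraries. These drew each gene independently, with its spread between replicates estimated over all groups. An earlier form of that simulation gave the nurse libraries no spread, which fixed its outcome, and was set aside after it had been run.

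The pipeline was tested on simulated data with 200 changed genes of a mean count of at least 200 in a forager against nurse comparison. edgeR recovered 44.8% of 67 genes changed 1.5-fold, 94.0% of 67 changed 2-fold and 100% of 66 changed 4-fold, with 11 false calls among 170. DESeq2 recovered 65.7%, 97.0% and 100%, with 35 false calls among 210. Plots were drawn with matplotlib 3.10.9.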

Results

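RNA from the antennae of honey bee (Apis mellifera) workers was sequenced on a DNBSEQ instrument in 12 libraries, 3 from each of 4 groups. The groups were newly emerged workers, nurses (workers that tend brood), foragers (workers that collect food outside the hive) and defenders. Ages, colonies, the number of bees per library and what the defenders had done are not given in the sources used here. The question taken from the series title is how antennal transcripts differ between workers that do different tasks. Since ages are not given, differences that go with task cannot be told apart from differences that go with age. The newly emerged libraries held 101317842, 66708813 and 92415714 counts and the nurse libraries 93601572, 76019071 and 96490617. The forager libraries held 100255711, 99999205 and 78207779 counts and the defender libraries 79995802, 119703929 and 106115595. The 10 most abundant genes of a library took 8.78% to 13.7% of its counts. Of 12319 genes in the count table, 208 had no count in any library and 11271 were tested. Levels below are in CPM, the count of a gene scaled to a common library size, given as mean ± SD over the 3 libraries of a group (n = 3), and p-values are from edgeR with Benjamini-Hochberg (BH) adjustment over the genes tested. Replicates of 1 group differed by more than counting noise, with a chi-square per gene of 54.4 to 344 between pairs of libraries; the highest, 344 and 276.5, were those of forager library 2 with forager libraries 1 and 3. The p-values measure the spread between these libraries, since the labels do not say whether they came from separate bees or colonies.

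Newly emerged antennae stood apart from those of the other 3 groups. On the first principal component of log2 CPM, which held 59.7% of the variance, the 3 newly emerged libraries lay between -68.8 and -63.6, and the nurse libraries between 7.55 and 15.0. The defender libraries lay between 21.7 and 24.8 and the forager libraries between 29.7 and 33.3. The second component held 11.9% of the variance, and on it nurse library 3 lay at -39.8 and nurse libraries 1 and 2 at -9.24 and -16.4. In a test of any difference among the 4 groups, 5472 genes (48.5%) passed. The group mean was highest in newly emerged workers for 2467 of these genes and lowest there for 2303. The median log2 fold change of all genes moved by 0.123 (nurse against newly emerged), 0.146 (forager against newly emerged) and -0.101 (defender against forager) when upper-quartile factors replaced the TMM factors used here. The share of calls that were higher is given with both kinds of factors for the 5 comparisons with calls.

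**Figure D1:**
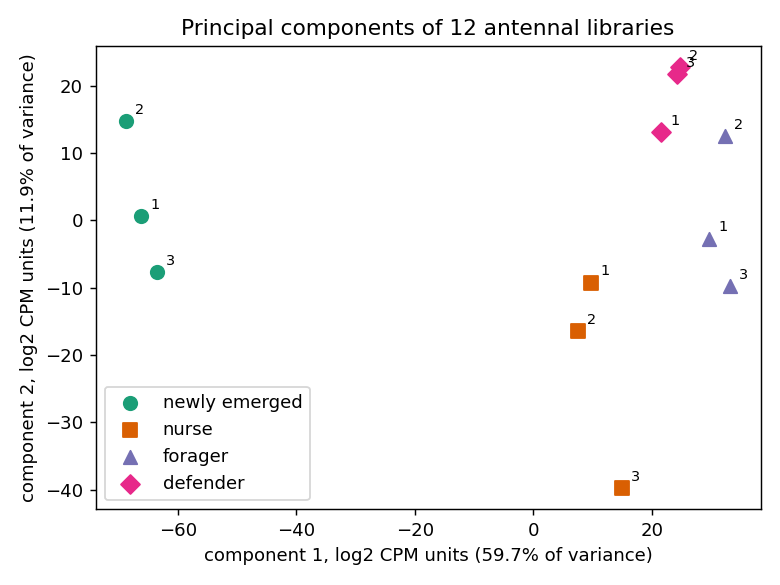
Each point is 1 library on the first 2 principal components of log2 CPM, with the percent of variance on each axis and the 4 worker groups in different colours. The newly emerged libraries lie between -68.8 and -63.6 on the first component and the lowest of the others at 7.55.

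The comparison of nurses with newly emerged workers asks how antennal transcripts differ between workers that have just left the cell and workers that tend brood. Transcripts of many structural cuticle proteins were lower in nurses. CPR6 was at 2.03 ± 0.926 CPM in nurses against 138 ± 32.6 in newly emerged workers (log2 fold change -6.08, SE 0.36, adjusted p = 3.96e-07). CPR19 fell from 277 ± 28.4 to 8.86 ± 3.87 CPM (log2 fold change -4.97, SE 0.40, adjusted p = 2.92e-06). The apidermin gene Apd-2 fell from 3886 ± 534 to 334 ± 72.0 CPM (log2 fold change -3.54, SE 0.30, adjusted p = 4.98e-06), and CPR27 fell by 3.27 on the log2 scale. Of 24 tested cuticle protein genes, 15 fell and 3 rose, also when adjusted over the list alone. The camera test gave adjusted p = 7.56e-05 for that list, and adjusted p = 0.147 with an estimated correlation. CPR22 was among the 3 that rose, from 77.2 ± 18.7 to 127 ± 28.6 CPM (adjusted p = 0.00924). TyHyd, which encodes tyrosine hydroxylase, fell from 3273 ± 682 to 297 ± 43.7 CPM (log2 fold change -3.46, SE 0.31, adjusted p = 6.88e-06). Of 4 yellow-family genes of cuticle tanning, 3 rose and 1 fell, also when adjusted over the list alone; the 1 that fell, Y-h, did not pass without newly emerged library 1 or 3 or without nurse library 1, 2 or 3. Y-f rose from 17.3 ± 0.937 to 64.2 ± 9.61 CPM (log2 fold change 1.89, SE 0.17, adjusted p = 9.48e-06). Beside these, 4 of 7 muscle troponin genes fell (4 also adjusted over the list alone; camera adjusted p = 0.0205, and adjusted p = 0.147 with an estimated correlation). The troponin C gene TpnCIIIa went from 922 ± 114 to 422 ± 66.0 CPM (adjusted p = 5e-05).

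Most of the listed odorant receptor and odorant binding protein genes, those with a symbol, rose in nurses. Of 34 odorant receptor genes, 20 rose and 1 fell (21 and 1 adjusted over the list alone; camera adjusted p = 3.32e-06, and adjusted p = 0.147 with an estimated correlation). Or12 rose from 56.4 ± 3.77 to 99.9 ± 5.88 CPM (log2 fold change 0.82, SE 0.09, adjusted p = 2.85e-05). Or11, the receptor for the main component of the queen pheromone, rose from 26.0 ± 2.62 to 45.1 ± 1.47 CPM (log2 fold change 0.80, SE 0.10, adjusted p = 0.000117). The receptor gene that fell was Or2, the shared odorant co-receptor, which went from 324 ± 15.9 to 176 ± 69.4 CPM (log2 fold change -0.88, SE 0.25, adjusted p = 0.0157). Of 19 odorant binding protein genes, 13 rose and 1 fell (14 and 2 adjusted over the list alone; camera adjusted p = 1.49e-05, and adjusted p = 0.147 with an estimated correlation). Obp21 rose from 128 ± 20.4 to 1071 ± 214 CPM (log2 fold change 3.06, SE 0.20, adjusted p = 7.32e-07), Obp16 from 410.4 ± 30.0 to 1673 ± 303 CPM (adjusted p = 8.12e-07), and Obp10 fell from 41.6 ± 6.48 to 26.1 ± 0.925 CPM (adjusted p = 0.000686). Of 5 chemosensory protein genes, 4 fell and none rose, also when adjusted over the list alone (camera adjusted p = 0.0442, and adjusted p = 0.147 with an estimated correlation). Without newly emerged library 3 the number that fell was 2. CSP2 went from 81.6 ± 17.9 to 30.6 ± 1.76 CPM and CSP4 from 1148 ± 75.2 to 604 ± 103 CPM (adjusted p = 4.33e-05 and 0.00139). Among the neuron and synapse markers, 2 of 6 rose and none fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.469); 1 rose without newly emerged library 2 or 3 or nurse library 2 or 3. Syt1, a synaptotagmin gene, went from 184 ± 14.1 to 234 ± 18.7 CPM (adjusted p = 0.00693). The glial marker Eaat-2 was at 22.7 ± 4.58 CPM in newly emerged workers and 21.0 ± 0.898 in nurses (adjusted p = 0.499).

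Gland-type secretory transcripts were much higher in nurse than in newly emerged antennae, and some of them varied between the nurse libraries. The family of major royal jelly proteins includes the main secreted proteins of the hypopharyngeal glands of the head. All 9 of its genes rose, also when adjusted over the list alone (camera adjusted p = 4.29e-06, and adjusted p = 0.147 with an estimated correlation). Mrjp1 was at 535 ± 609 CPM in nurses and 1.11 ± 0.525 in newly emerged workers (log2 fold change 8.91, SE 1.53, adjusted p = 0.00101), with 1236, 238 and 132 CPM in the 3 nurse libraries. Mrjp3 was at 276 ± 242 against 2.08 ± 1.03 CPM (adjusted p = 0.000831), and Mrjp9 at 276 ± 19.0 against 78.9 ± 2.98 CPM (adjusted p = 6.92e-06). The gland marker list holds these 9 genes and 2 alpha-glucosidase genes, and 10 of its 11 members rose (10 adjusted over the list alone; camera adjusted p = 1.73e-06, and adjusted p = 0.147 with an estimated correlation). Hbg3, a hypopharyngeal gland alpha-glucosidase, rose from 21.8 ± 3.67 to 111 ± 16.9 CPM (log2 fold change 2.35, SE 0.16, adjusted p = 9.71e-07). The storage protein genes Hex70a and Hex110 rose, Hex70a from 3.14 ± 1.61 to 36.3 ± 21.6 CPM (log2 fold change 3.52, SE 0.78, adjusted p = 0.00434). Both were called among the 3 tested genes of vitellogenin and the hexamerins (3 adjusted over the list alone). Vg, the yolk protein vitellogenin, was at 35.4 ± 5.56 CPM in newly emerged workers and 77.4 ± 58.5 in nurses (adjusted p = 0.0634, and 0.00293 without nurse library 1). The single hemocyte marker, the prophenoloxidase gene PPO, rose from 22.8 ± 1.36 to 36.8 ± 11.3 CPM (adjusted p = 0.00744). Its log2 fold change was 0.69, and 0.44 without nurse library 1.

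Smaller gene groups moved both ways between newly emerged workers and nurses. Over all tested genes 39.6% were called in this comparison, so called members in a short list do not by themselves set it apart. Of 8 genes of amine receptors and synthesis, 1 rose and 4 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.244). The serotonin receptor gene 5-HT1 rose from 3.93 ± 0.207 to 11.5 ± 2.40 CPM and the dopamine receptor gene Dop3 fell from 5.29 ± 0.898 to 1.46 ± 0.552 CPM (adjusted p = 3.22e-05 and 0.000616). Of 4 listed cytochrome P450 genes, 2 rose and 1 fell, also when adjusted over the list alone. CYP6AQ1 rose from 5079.6 ± 516 to 13239 ± 811 CPM and Cyp4g11 from 39.1 ± 14.5 to 171 ± 40.1 CPM (adjusted p = 1.11e-05 and 0.00083). Of 5 genes of antimicrobial peptides and recognition, 3 rose, also when adjusted over the list alone (camera adjusted p = 0.0354, and adjusted p = 0.147 with an estimated correlation). PGRP-S3, a peptidoglycan recognition protein gene, went from 5.07 ± 1.25 to 12.6 ± 1.55 CPM (adjusted p = 0.000207). All 3 listed ribosomal protein genes rose, also when adjusted over the list alone. RpL32 went from 58.6 ± 5.04 to 95.9 ± 10.8 CPM (adjusted p = 0.000421). The list matched by the gustatory receptor pattern holds Gr10 together with Grd and Grp, which are not numbered gustatory receptors. Gr10 rose from 3.00 ± 0.168 to 5.49 ± 0.803 CPM and Grp fell from 31.7 ± 8.38 to 0.732 ± 0.0489 CPM (adjusted p = 0.00148 and 3.28e-08), 1 and 1 also when adjusted over the list alone. Among 7 genes of the juvenile hormone and ecdysone pathway, 3 rose and 1 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.52). Without newly emerged library 1 none rose, without newly emerged library 2, nurse library 1 or nurse library 3 only 1 did, and without nurse library 3 the number that fell was 2. E74 went from 157 ± 5.98 to 91.3 ± 17.6 CPM (adjusted p = 0.000528). Of 4 photoreceptor markers, 1 rose and 1 fell, also when adjusted over the list alone; none rose without newly emerged library 1 or 2 or nurse library 1. The blue opsin gene Blop went from 7.43 ± 2.59 to 3.24 ± 1.25 CPM (adjusted p = 0.00717).

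Over all genes, 4460 differed between nurses and newly emerged workers, 2126 of them higher and 2334 lower in nurses, and 1319 by at least 2-fold. In 4307 of the 4460, all 3 libraries of 1 group lay above all 3 of the other; over all tested genes this held for 52.3%, where chance gives 10%. The share higher in nurses was 47.7% with TMM factors and 63.9% with upper-quartile factors, while with the latter 23 odorant receptors rose and 1 fell and 3 cuticle proteins rose and 14 fell. In the remaining lists, glutathione S-transferases had 1 higher and 1 lower of 3 (1 and 1 adjusted over the list alone), neuropeptides 0 higher and 1 lower of 5 (0 and 1; camera adjusted p = 0.117), heat shock proteins 1 higher of 4 (0) and oxidative phosphorylation 1 lower of 2 (2). Venom components, the clock and glia, 1 tested gene each, had no call by edgeR; 1 of these 3 genes passed at unadjusted p under 0.05 and 0 with DESeq2. The clock gene Per was at 80.9 ± 4.04 CPM in newly emerged workers and 79.5 ± 11.5 in nurses (adjusted p = 0.925). The venom gene Melt was at 0.0566 ± 0.0127 and 0.144 ± 0.0565 CPM (adjusted p = 0.0568, and 0.0323 without nurse library 1). With 1 tested gene in its list, adjustment over the list alone leaves the unadjusted p of Melt, which passed. Of 57 named calls, 48 held whichever of the 6 libraries was left out. The other calls were those of Br-c (0.38), Cox6c (-0.57), Eth (-0.87), GstS1 (1.25, and 2.01 without newly emerged library 1), Hsp90 (0.86), Kr-h1 (1.12), Lop1 (2.87, and 1.52 without nurse library 1), Syx1A (0.38) and Y-h (-0.56; log2 fold changes). Leaving out newly emerged library 1, 2 or 3 ended 5, 5 and 4 of these calls, and leaving out nurse library 1, 2 or 3 ended 6, 7 and 4, at adjusted p = 0.0502 to 0.173.

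**Figure D2:**
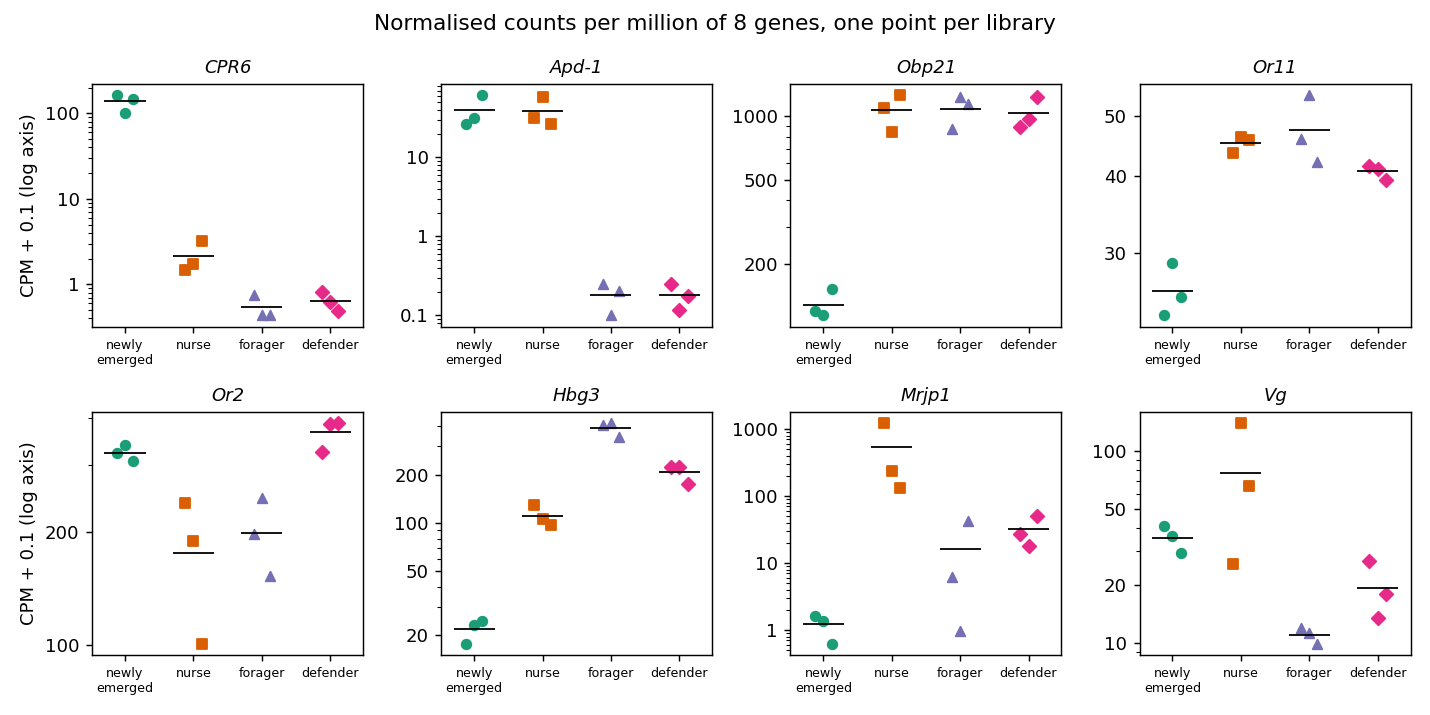
CPM of 8 genes on a log axis (0.1 added) in the 4 groups, with 1 point per library and a line at the group mean. CPR6 drops from 138 ± 32.6 CPM in newly emerged workers to 2.03 ± 0.926 in nurses, while Obp21 goes from 128 ± 20.4 to 1071 ± 214 CPM.

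The comparison of foragers with nurses sets work outside the hive against brood care inside it. Some cuticle transcripts were lower in foragers than in nurses. The apidermin gene Apd-1 fell from 38.9 ± 16.8 to 0.0840 ± 0.0765 CPM (log2 fold change -8.85, SE 0.67, adjusted p = 6.64e-05), Apd-3 from 2.41 ± 0.977 to 0.130 ± 0.0461 CPM and CPR19 from 8.86 ± 3.87 to 1.15 ± 0.562 CPM (adjusted p = 0.000682 and 0.00214). Of 24 cuticle protein genes, 7 fell and 1 rose (9 and 2 adjusted over the list alone; camera adjusted p = 0.000891, and adjusted p = 0.251 with an estimated correlation); none rose without nurse library 1 or 2 or forager library 2. Hbg3 rose from 111 ± 16.9 to 390.0 ± 39.5 CPM (log2 fold change 1.81, SE 0.16, adjusted p = 0.000128), while royal jelly protein genes fell. Mrjp3 was at 2.24 ± 3.16 CPM in foragers against 276 ± 242 in nurses and Mrjp4 at 0.309 ± 0.198 against 19.2 ± 16.2 CPM (adjusted p = 0.00835 and 0.00112). Of 9 royal jelly protein genes, 5 fell and 0 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.000891, and adjusted p = 0.251 with an estimated correlation). The number that fell was 3 without nurse library 1 and 2 without forager library 1 or forager library 2. In the gland marker list, which holds these genes, 5 of 11 fell and 1 rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.0136, and adjusted p = 0.293 with an estimated correlation), with 3, 2 and 2 lower genes without the same libraries. Vg fell from 77.4 ± 58.5 to 10.9 ± 1.03 CPM (log2 fold change -2.82, SE 0.48, adjusted p = 0.00769), 1 of 3 genes of vitellogenin and the hexamerins that all fell, also when adjusted over the list alone; without forager library 2 only 1 of the 3 fell. PPO, the hemocyte marker, fell from 36.8 ± 11.3 to 9.63 ± 0.373 CPM (log2 fold change -1.93, SE 0.18, adjusted p = 0.000199).

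Carriers of chemical signals moved in both directions between nurses and foragers. CSP2 fell from 30.6 ± 1.76 to 11.1 ± 1.53 CPM (log2 fold change -1.47, SE 0.16, adjusted p = 0.000691) and Obp16 rose from 1673 ± 303 to 2825 ± 287 CPM (log2 fold change 0.76, SE 0.13, adjusted p = 0.00881). It was the single gene of 19 for odorant binding proteins that passed (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.3), and 2 rose without nurse library 3. Gr10 fell from 5.49 ± 0.803 to 2.63 ± 0.299 CPM and Dat rose from 26.6 ± 2.90 to 51.0 ± 3.93 CPM (adjusted p = 0.00471 and 0.00855). None of 34 odorant receptor genes passed in edgeR, also when adjusted over the list alone; 5 were higher and 0 lower at unadjusted p under 0.05, and DESeq2 called 2 higher. Their camera test gave adjusted p = 0.00493 for higher levels, and adjusted p = 0.447 with an estimated correlation. Or11 was at 45.1 ± 1.47 CPM in nurses and 47.3 ± 6.09 in foragers, and Or2 at 176 ± 69.4 and 198 ± 46.8 CPM (adjusted p = 0.789 and 0.781). Of 5 chemosensory protein genes, 1 rose and 2 fell (2 and 2 adjusted over the list alone); 1 fell without nurse library 1 or 2 or forager library 1 or 3, and none rose without nurse library 2. Their median log2 fold change was 0.24, the mean -0.10, and the camera direction down (adjusted p = 0.731). Muscle markers fell for 2 of 7 genes and rose for 0 (4 and 1 adjusted over the list alone; camera adjusted p = 0.0136, and adjusted p = 0.251 with an estimated correlation), and the numbers that fell were 4, 0 and 1 without nurse library 1, nurse library 2 and forager library 2. Of 5 antimicrobial and recognition genes, 1 rose (2 adjusted over the list alone; camera adjusted p = 0.0292, and adjusted p = 0.251 with an estimated correlation), and none without nurse library 2 or forager library 1.

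In all, 452 genes differed between foragers and nurses, 215 higher and 237 lower in foragers, and 171 by at least 2-fold. In 451 of them the 3 libraries of 1 group lay above the 3 of the other; over all tested genes 18.1% did, where chance gives 10%. The share higher was 47.6% with TMM and 53.0% with upper-quartile factors, and 449 were higher and 436 lower with DESeq2, so these calls show no direction that holds under each fit; higher calls were also the more numerous without newly emerged library 3 (199 and 193) or forager library 3 (267 and 243). The count was 176 without nurse library 2, 259 without forager library 1, 288 without forager library 2, 885 with DESeq2 and 111 with only the 6 libraries of these groups in the fit. That last fit ended 15 of the 27 named calls, at adjusted p = 0.0559 to 0.221, among them those of Mrjp3, Obp16 and Vg (0.0794, 0.0868 and 0.0578). The 13 lists without a call hold 79 genes, of which 10 were higher and 6 lower at unadjusted p under 0.05 and 3 higher and 4 lower with DESeq2. The ribosomal protein gene RpL35 was at 122 ± 10.1 CPM in nurses and 160.3 ± 11.6 in foragers (adjusted p = 0.0574, and 0.0391 without nurse library 3), and Kr-h1, a juvenile hormone response factor, at 31.6 ± 14.2 and 41.7 ± 10.4 CPM (adjusted p = 0.548). Of 27 named calls, 12 held whichever of the 6 libraries was left out. The 15 others were those of AGLU2 (0.65), Blop (-1.25), CPR21 (1.48), CSP3 (0.87), CSP4 (-0.71), Def2 (2.74), Hex110 (-3.38), Hex70a (-4.44), Mrjp1 (-5.05), Mrjp2 (-4.92), TpnCI (-1.34), TpnCIIb (-0.95), Trxr-1 (0.48), TyHyd (1.41) and Y-f (0.83; log2 fold changes). Leaving out nurse library 1, 2 or 3 ended 7, 13 and 1 of them, and forager library 1, 2 or 3 ended 9, 9 and 2, at adjusted p = 0.0514 to 0.2. CSP3, among the most abundant of these, was at 4192 ± 857 CPM in nurses and 7653 ± 628 in foragers (adjusted p = 0.0132).

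The comparison of defenders with nurses sets hive defence against brood care. Some cuticle transcripts were lower in defenders than in nurses. Apd-1 fell from 38.9 ± 16.8 to 0.0815 ± 0.0680 CPM (log2 fold change -9.03, SE 0.68, adjusted p = 8.72e-05), Apd-2 from 334 ± 72.0 to 57.8 ± 18.6 CPM (log2 fold change -2.53, SE 0.29, adjusted p = 0.0011) and CPR19 from 8.86 ± 3.87 to 1.16 ± 0.506 CPM (adjusted p = 0.00345). Apd-3 fell by 4.12 on the log2 scale. Of 24 cuticle protein genes, 9 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 0.000201, and adjusted p = 0.247 with an estimated correlation). The number that fell was 5 without nurse library 2 and 4 without defender library 2 or defender library 3, and none rose when any 1 of the 6 libraries was left out. Hbg3 rose from 111 ± 16.9 to 208 ± 28.7 CPM (log2 fold change 0.90, SE 0.15, adjusted p = 0.00986) and Mrjp4 fell from 19.2 ± 16.2 to 0.750 ± 0.240 CPM (log2 fold change -4.68, SE 0.67, adjusted p = 0.00552). Of 9 royal jelly protein genes, 3 fell and 1 rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.0978); without defender library 1, 2 or 3 the number that fell was 1 each time, and none rose without nurse library 2 or 3 or defender library 2 or 3. In the gland list that contains them, 3 fell and 2 rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.19); 1 fell without defender library 1, 2 or 3, and 1 rose without nurse library 2 or 3 or defender library 2 or 3. CSP2 fell from 30.6 ± 1.76 to 12.5 ± 1.83 CPM and the hemocyte marker PPO from 36.8 ± 11.3 to 11.4 ± 0.927 CPM (adjusted p = 0.00193 and 0.000562). Of 34 odorant receptor genes, 1 rose and none fell (1 adjusted over the list alone; camera adjusted p = 0.073). It was Or2, at 366 ± 35.3 CPM in defenders and 176 ± 69.4 in nurses (log2 fold change 1.06, SE 0.25, adjusted p = 0.0309), a call that ended without nurse library 2 or without defender library 1, 2 or 3.

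In all, 872 genes differed between defenders and nurses, 522 higher and 350 lower in defenders, and 216 by at least 2-fold. In 869 of them the libraries of the groups were separated, as in 38.0% of all tested genes, where chance gives 10%. The share higher was 59.9% with TMM and 41.1% with upper-quartile factors, and the direction of the excess was thus not the same under both. Lower calls were also the more numerous with only these 2 groups in the fit (177 higher, 254 lower), without nurse library 2 (63 and 93) or 3 (154 and 155), and without defender library 1 (126 and 163), 2 (47 and 74) or 3 (41 and 58). The count was 1428 without nurse library 1, 156 without nurse library 2 and 309 without nurse library 3. It was 289, 121 and 99 without defender library 1, 2 and 3, 554 without newly emerged library 1, 1841 with DESeq2 and 431 with only these 2 groups in the fit, which ended 12 of the 29 named calls (adjusted p = 0.0524 to 0.0787). The neuron and synapse markers Para, a voltage-gated sodium channel gene, and brp, an active zone gene, were 2 of 3 that fell among 6 (3 adjusted over the list alone; camera adjusted p = 0.073); none fell without nurse library 2 or 3 or defender library 2 or 3, and 1 without defender library 1. Para was at 1239 ± 35.9 CPM in defenders and 1647 ± 173 in nurses and brp at 296 ± 53.1 and 431 ± 19.5 CPM (adjusted p = 0.0274 and 0.0282). Muscle markers fell for 3 of 7 genes (3 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.073), and for 1 without nurse library 2 or defender library 1, 2 or 3. TpnCI went from 251 ± 70.8 to 80.9 ± 34.3 CPM (adjusted p = 0.00856). All 3 genes of vitellogenin and the hexamerins fell, also when adjusted over the list alone, and none did without nurse library 2 or 3 or defender library 2 or 3. Of 29 named calls, 8 held whichever of the 6 libraries was left out. The 21 others included these of Para, brp, TpnCI and Or2 and those of Mrjp2 (-4.01, and -2.52 without nurse library 1), Mrjp3 (-5.81), Mrjp9 (0.70), Vg (from 77.4 ± 58.5 to 19.3 ± 6.76 CPM, and log2 fold change -1.24 without nurse library 2), Hex70a (-2.77), Hex110 (-2.69, and -1.68 without nurse library 2), AGLU2 (0.55), Blop (-1.43), Br-c (-0.53), CPR3 (0.70), CSP4 (-0.73), Dat (0.72), Def2 (2.47), Gpdh (0.46), GstS4 (-1.31), Nedd9 (0.78) and TpnCIIb (-1.05; log2 fold changes). Leaving out nurse library 1, 2 or 3 ended 2, 18 and 14 of them, and defender library 1, 2 or 3 ended 13, 20 and 20, at adjusted p = 0.0504 to 0.156. The 12 lists without a call hold 55 genes, of which 6 were higher and 4 lower at unadjusted p under 0.05 and 4 higher and 3 lower with DESeq2. Mrjp1 was at 31.8 ± 16.8 CPM in defenders and 535 ± 609 in nurses, Or11 at 40.6 ± 1.11 and 45.1 ± 1.47 CPM, and Kr-h1 at means of 41.1 and 31.6 CPM (adjusted p = 0.0589, 0.363 and 0.447).

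The comparison of defenders with foragers sets hive defence against foraging. No gene passed in edgeR with all 12 libraries; the smallest adjusted p was 0.0544. At unadjusted p under 0.05 there were 2705 genes, where chance gives 564, and in 3605 genes (32.0%) the libraries of the groups were separated, where chance gives 10%. The number of genes called was 1273 with DESeq2, 876 with only these 2 groups in the fit and 667 with a term for the number the libraries share. It was 491 without nurse library 1, 1161 without nurse library 3 and 1 without forager library 2. DESeq2, the fit of these 2 groups and the fit with the number term called 559 genes in common with 1 sign, 474 higher and 85 lower in defenders. The single fits called 786 higher and 487 lower (DESeq2), 711 and 165 (these 2 groups) and 542 and 125 (number term). With upper-quartile factors the latter 2 gave 402 and 405, and 342 and 381, so the excess of higher calls depends on the scaling. From the 559 genes, 8 with a symbol, separated libraries and at least 5 CPM were taken after their values were seen. Or2 was at 366 ± 35.3 CPM in defenders and 198 ± 46.8 in foragers (log2 fold change 0.88, SE 0.25, adjusted p = 0.0737; 0.0431 with the number term). Nedd9 was at 72.1 ± 5.12 and 42.5 ± 7.06 CPM, Fem (feminizer) at 114 ± 6.92 and 78.9 ± 8.49 CPM and Dcr-1 (Dicer) at 28.3 ± 1.81 and 21.7 ± 1.45 CPM (adjusted p = 0.0665, 0.0544 and 0.0715). Hbg3 was at 208 ± 28.7 CPM in defenders and 390.0 ± 39.5 in foragers (log2 fold change -0.91, SE 0.15, adjusted p = 0.0544; 0.0256 with the number term). CSP3 was at 5142 ± 359 and 7653 ± 628 CPM, CSP6 at 14.2 ± 3.53 and 32.8 ± 10.5 CPM and RpL35 at 121 ± 6.89 and 160.3 ± 11.6 CPM (adjusted p = 0.0766, 0.0544 and 0.0625). The 25 lists hold 165 tested genes, none called by edgeR with all 12 libraries and no number term. Of these, 5 were higher and 15 lower at unadjusted p under 0.05 and 2 higher and 8 lower with DESeq2. With the number term edgeR called 1 odorant receptor gene higher, and 2 chemosensory protein genes, 1 ribosomal protein gene and 1 gland gene lower. The fit of these 2 groups called the same numbers in these lists and 2 antimicrobial and recognition genes lower. Adjusted over the list alone, the gland list had 1 lower gene, ribosomal proteins 3, chemosensory proteins 2, oxidative phosphorylation 1, and the gustatory list 1 higher and 1 lower. Camera gave no list, with 0.129 as the smallest adjusted p (royal jelly proteins), and adjusted p = 0.771 with an estimated correlation. Or11 was at 40.6 ± 1.11 CPM in defenders and 47.3 ± 6.09 in foragers and Vg at 19.3 ± 6.76 and 10.9 ± 1.03 CPM (adjusted p = 0.209 and 0.29).

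**Figure D3:**
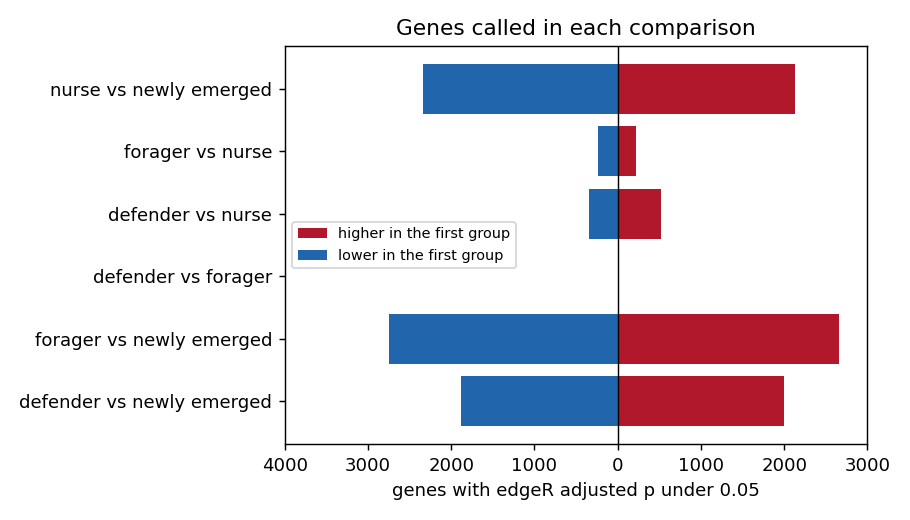
Bars give the number of genes with an edgeR adjusted p under 0.05 that were higher (to the right of 0) or lower (to the left) in the first-named group of each of the 6 comparisons. The bars reach 2655 and 2748 for foragers against newly emerged workers and 0 for defenders against foragers.

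The comparison of foragers with newly emerged workers spans the ends of the first component. CPR6 fell from 138 ± 32.6 to 0.444 ± 0.186 CPM (log2 fold change -8.26, SE 0.41, adjusted p = 4.82e-08), Apd-1 from 40.2 ± 19.3 to 0.0840 ± 0.0765 CPM and Apd-2 from 3886 ± 534 to 65.6 ± 25.6 CPM (adjusted p = 1.02e-06 and 1.17e-07). Of 24 cuticle protein genes, 16 fell and 4 rose (16 and 5 adjusted over the list alone; camera adjusted p = 3.19e-05, and adjusted p = 0.203 with an estimated correlation). Of 34 odorant receptor genes, 23 rose and 1 fell (23 and 1 adjusted over the list alone; camera adjusted p = 7.11e-07, and adjusted p = 0.228 with an estimated correlation). The 1 that fell, Or2, did not pass without newly emerged library 1, 2 or 3 or forager library 1 or 3. Or9 rose from 2.57 ± 0.379 to 6.80 ± 0.430 CPM and Or11 from 26.0 ± 2.62 to 47.3 ± 6.09 CPM (adjusted p = 9e-06 and 3.83e-05). Of 19 odorant binding protein genes, 14 rose and 2 fell (14 and 3 adjusted over the list alone; camera adjusted p = 7.99e-05, and adjusted p = 0.228 with an estimated correlation), and 1 fell without newly emerged library 3 or forager library 1 or 3. Obp19 rose from 23.4 ± 1.69 to 285 ± 51.5 CPM and Obp16 from 410.4 ± 30.0 to 2825 ± 287 CPM (adjusted p = 6.99e-07 and 5.17e-08). Hbg3 rose from 21.8 ± 3.67 to 390.0 ± 39.5 CPM (log2 fold change 4.16, SE 0.17, adjusted p = 1.3e-08), with 5 of 11 gland markers higher (6 adjusted over the list alone; camera adjusted p = 0.0115, and adjusted p = 0.294 with an estimated correlation). Of 9 royal jelly protein genes, 4 rose (5 adjusted over the list alone; camera adjusted p = 0.0378, and adjusted p = 0.362 with an estimated correlation), Mrjp9 from 78.9 ± 2.98 to 409.8 ± 85.7 CPM (adjusted p = 4.61e-07). Apid1, the antimicrobial peptide apidaecin, rose from 10.3 ± 8.35 to 104 ± 16.9 CPM (adjusted p = 0.000245), 1 of 4 genes of 5 in its list that rose (4 adjusted over the list alone; camera adjusted p = 0.00776, and adjusted p = 0.203 with an estimated correlation). Kr-h1 rose from 14.6 ± 3.26 to 41.7 ± 10.4 CPM (adjusted p = 0.00173). Vg fell from 35.4 ± 5.56 to 10.9 ± 1.03 CPM and PPO from 22.8 ± 1.36 to 9.63 ± 0.373 CPM (adjusted p = 0.00943 and 0.000134). Muscle markers fell for 6 of 7 genes (6 adjusted over the list alone; camera adjusted p = 0.00304, and adjusted p = 0.203 with an estimated correlation).

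In all, 5403 genes differed between foragers and newly emerged workers, 2655 higher and 2748 lower in foragers, 1805 by at least 2-fold, and 5546 with the number term. In 5202 the libraries were separated, as in 56.3% of all tested genes, where chance gives 10%. The share higher was 49.1% with TMM and 65.2% with upper-quartile factors, with which 25 odorant receptors rose and none fell. Higher calls were also the more numerous when newly emerged library 1 (2290 and 2219), 2 (2176 and 2111) or 3 (2609 and 2530) or defender library 1 (2667 and 2545), 2 (2657 and 2524) or 3 (2620 and 2505) was left out. The clock and heat shock lists (5 genes) had no call in edgeR with all 12 libraries; 0 were higher and 1 lower at unadjusted p under 0.05. DESeq2 called 1 lower, Hsc70-3, which also passed without forager library 2 (adjusted p = 0.0312 and 0.0207). Of 54 named calls, 45 held whichever of the 6 libraries was left out. The others were those of Or2 (-0.71), Mrjp1 (3.86, and 1.64 without forager library 3; adjusted p = 0.0914 with the number term), Syx1A (0.33), Syt20 (-0.39), Eaat-2 (-0.33, and -0.15 without newly emerged library 3), CSP1 (0.53), Cox6b1 (-0.37), Obp13 (-2.98) and Y-h (-0.73; log2 fold changes). Leaving out newly emerged library 1, 2 or 3 ended 7, 7 and 6 of them, and forager library 1, 2 or 3 ended 4, 3 and 8, at adjusted p = 0.0519 to 0.239. Or2 was at 198 ± 46.8 CPM in foragers and 324 ± 15.9 in newly emerged workers.

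Compared with newly emerged workers, defenders had lower levels of most listed cuticle protein genes. Levels of most listed odorant receptor genes were higher in defenders. CPR6 fell from 138 ± 32.6 to 0.543 ± 0.168 CPM (log2 fold change -8.01, SE 0.40, adjusted p = 5.76e-08) and Apd-2 from 3886 ± 534 to 57.8 ± 18.6 CPM (adjusted p = 1.14e-07). Of 24 cuticle protein genes, 16 fell and 4 rose, also when adjusted over the list alone (camera adjusted p = 8.44e-07, and adjusted p = 0.0868 with an estimated correlation). The number that rose was 2 without newly emerged library 2 or without defender library 1. Of 34 odorant receptor genes, 20 rose and none fell (22 and 0 adjusted over the list alone; camera adjusted p = 3.63e-08, and adjusted p = 0.114 with an estimated correlation). Or58 rose from 2.74 ± 0.317 to 5.54 ± 0.407 CPM and Or12 from 56.4 ± 3.77 to 100.5 ± 3.34 CPM (adjusted p = 5.99e-05 and 1.64e-05). Or2 was at 366 ± 35.3 CPM in defenders and 324 ± 15.9 in newly emerged workers (adjusted p = 0.626). Of 19 odorant binding protein genes, 12 rose and 1 fell (14 and 2 adjusted over the list alone; camera adjusted p = 7.39e-05, and adjusted p = 0.161 with an estimated correlation), and 2 fell without defender library 2. Obp19 rose from 23.4 ± 1.69 to 249.7 ± 58.3 CPM (adjusted p = 1.09e-06). Of 5 chemosensory protein genes, 3 fell (3 adjusted over the list alone; camera adjusted p = 0.0116, and adjusted p = 0.0868 with an estimated correlation). Hbg3 rose from 21.8 ± 3.67 to 208 ± 28.7 CPM (log2 fold change 3.25, SE 0.17, adjusted p = 6.32e-08). Of 9 royal jelly protein genes, 6 rose (7 adjusted over the list alone; camera adjusted p = 0.000449, and adjusted p = 0.164 with an estimated correlation), and of 11 gland markers 7 (8 adjusted over the list alone; camera adjusted p = 0.000244, and adjusted p = 0.114 with an estimated correlation). Without newly emerged library 3 these numbers were 3 and 4. Antimicrobial and recognition genes rose for 4 of 5 (4 adjusted over the list alone; camera adjusted p = 0.00832) and muscle markers fell for 6 of 7 (6 adjusted over the list alone; camera adjusted p = 0.000473), each at adjusted p = 0.0868 with an estimated correlation. TpnCIIa went from 50.1 ± 6.14 to 11.6 ± 1.10 CPM (adjusted p = 2.93e-06), and PPO fell from 22.8 ± 1.36 to 11.4 ± 0.927 CPM (adjusted p = 0.000746).

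In all, 3880 genes differed between defenders and newly emerged workers, 1994 higher and 1886 lower in defenders, 1397 by at least 2-fold, 4043 with the number term and 2579 with the stricter filter on low counts. In 3846 the libraries were separated, as in 54.8% of all tested genes, where chance gives 10%. The share higher was 51.4% with TMM and 57.6% with upper-quartile factors, while lower calls were the more numerous with DESeq2 (2117 higher, 2130 lower) and with only these 2 groups in the fit (2304 and 2440). The clock list and the list of vitellogenin and the hexamerins (4 genes) had no call by edgeR with all 12 libraries, with 0 genes at unadjusted p under 0.05 and 0 with DESeq2, and Vg was at 19.3 ± 6.76 CPM in defenders and 35.4 ± 5.56 in newly emerged workers (adjusted p = 0.154, and 0.0209 with only these 2 groups in the fit). The clock gene Per passed without defender library 2 (adjusted p = 0.0283). Of 56 named calls, 43 held whichever of the 6 libraries was left out. The others were those of Mrjp1 (4.84), Mrjp2 (3.71), Mrjp5 (3.94), Syx1A (0.32; adjusted p = 0.0609 with the number term), Para (-0.34), Nrx-1 (-0.61), Tk (-0.41), E75 (0.94), Eaat-2 (-0.37, and -0.20 without newly emerged library 3), GstD1 (-0.46), GstS1 (1.53), Hsc70-3 (-0.29) and Y-h (-0.59; log2 fold changes). Leaving out newly emerged library 1, 2 or 3 ended 7, 8 and 9 of them, and defender library 1, 2 or 3 ended 9, 4 and 9, at adjusted p = 0.0504 to 0.196.

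Changes from nurse to forager and from newly emerged worker to defender share no library and went the same way in 342 genes called in both, 171 higher and 171 lower, where lists drawn independently would share 38.0 and 39.7. A further 21 were called in opposite directions. Both comparisons come from 1 fit with a common spread per gene, so genes with a small spread pass more readily in each. The numbers for independent lists are thus low benchmarks, here and for the comparisons with nurses below. The number shared was 614 with DESeq2 and 226 with the stricter filter on low counts. Across the 11271 genes, which are not independent replicates, the Pearson correlation of the log2 fold changes was 0.455. Foragers and defenders were both compared with the same nurse libraries, and 253 genes were called in both comparisons with 1 sign, 97 higher and 156 lower, and 0 with opposite signs. Independent lists would share 9.96 and 7.36, and DESeq2 gave 483 shared genes. In 20 simulations without any group effect against shared nurse libraries, the mean number shared was 0.05 and the highest 1. Without a group effect hardly any gene can pass in either comparison, so that number was bound to be low. It does not show how many calls common nurse libraries would make coincide. The correlation across genes was 0.652, against 0.475 to 0.535 in the simulations, and the covariance 0.124 against a mean of 0.0289. The simulations drew each gene independently, with a spread taken from all groups and not from the nurse libraries alone. A change that many genes of a nurse library share is thus not in them, and they can understate what common nurse libraries give. With the nurse libraries divided between the comparisons, 1 for foragers or defenders and 2 for the other, 20 to 133 genes were shared with 1 sign and at most 38 with opposite signs in the 6 divisions. Independent lists would share 0.441 to 41.0 with 1 sign. A lone nurse library is there assumed to vary like the other groups. The correlation ran from 0.167 to 0.575 and the covariance from 0.0482 to 0.126, with fewer nurse libraries per comparison than in the fit above, so part of the shared change can come from the common nurse libraries. The simulations also left out what libraries of 1 number share: residuals of foragers and defenders of 1 number were correlated at 0.222 to 0.423, which can add to the genes shared in either pair of comparisons.

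Splicing was given as inclusion levels, the fraction of a splice event's reads that include the exon or part, for 491 events in 332 genes. They comprised 288 skipped exons, 90 mutually exclusive exon pairs, 26 retained introns, 43 alternative 3' splice sites and 44 alternative 5' splice sites. Depth per event is unknown. In Syx1A, the syntaxin gene, the alternative 3' splice site event at positions 16183445 to 16183809 (1-based, build not given in the sources used here) had an inclusion level of 0.404 ± 0.0357 (SD, n = 3) in newly emerged workers. It was 0.697 ± 0.0275 in nurses, 0.719 ± 0.0189 in foragers and 0.693 ± 0.0243 in defenders. The skipped exon of Or58 at 10143897 to 10143996 was included at 0.327 ± 0.0323 in newly emerged workers, 0.558 ± 0.217 in nurses, 0.745 ± 0.0678 in foragers and 0.624 ± 0.0455 in defenders. The mutually exclusive exons of 5-HT1, at 4753620 to 4754086 and 4763105 to 4763238, had inclusion levels of 0.321 ± 0.168, 0.532 ± 0.166, 0.725 ± 0.0557 and 0.647 ± 0.0601 in the same order. Strand is not given, so which exon of such a pair the level counts is not known. Dscam, a neuronal adhesion molecule gene, had 9 of the 12 named events, and all 9 had higher mean inclusion in nurses and in defenders than in newly emerged workers; the libraries were separated in 6 and 8 of them. In foragers, 6 of the 9 had higher and 3 lower mean inclusion than in newly emerged workers, with separated libraries in 2, and 2 had higher and 7 lower mean inclusion than in nurses, with separated libraries in 1. The Dscam events are not independent, since each of its mutually exclusive pairs shares an exon with another and its skipped exons lie close together. They were also chosen for large differences between these groups, with neural genes taken first. The tallies thus describe linked, selected events and do not count separate pieces of evidence. For the mutually exclusive pairs among them, higher inclusion refers to an exon that is not known, so the sign there has no set meaning. The Dscam skipped exon at 11874756 to 11874917 was included at 0.373 ± 0.11, 0.747 ± 0.223, 0.29 ± 0.122 and 0.618 ± 0.149. For events with separated libraries the two-sided exact permutation p is 0.1, the smallest that 3 against 3 can give, so no single event can pass 0.05.

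Every event had a difference between 2 group means of at least 0.201, so the events appear chosen on these samples, and no share that chance gives is a fair benchmark for the counts of events. In 237 of 491 events (48.3%) all 3 newly emerged libraries lay outside the range of the other 9, and the libraries of nurses did so in 17 events, of foragers in 18 and of defenders in 11. Libraries were separated in 333 events between nurses and newly emerged workers (181 with higher inclusion in nurses, 152 lower) and in 143 between foragers and nurses (66 and 77). They were separated in 147 events between defenders and nurses (59 and 88), 82 between defenders and foragers (38 and 44), 357 between foragers and newly emerged workers (183 and 174) and 383 between defenders and newly emerged workers (193 and 190). These counts include mutually exclusive pairs, for which higher or lower refers to an exon that is not known. Of the separated events, 57 between foragers and nurses, 32 between defenders and nurses and 23 between defenders and foragers differed by at least 0.2.

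**Figure D4:**
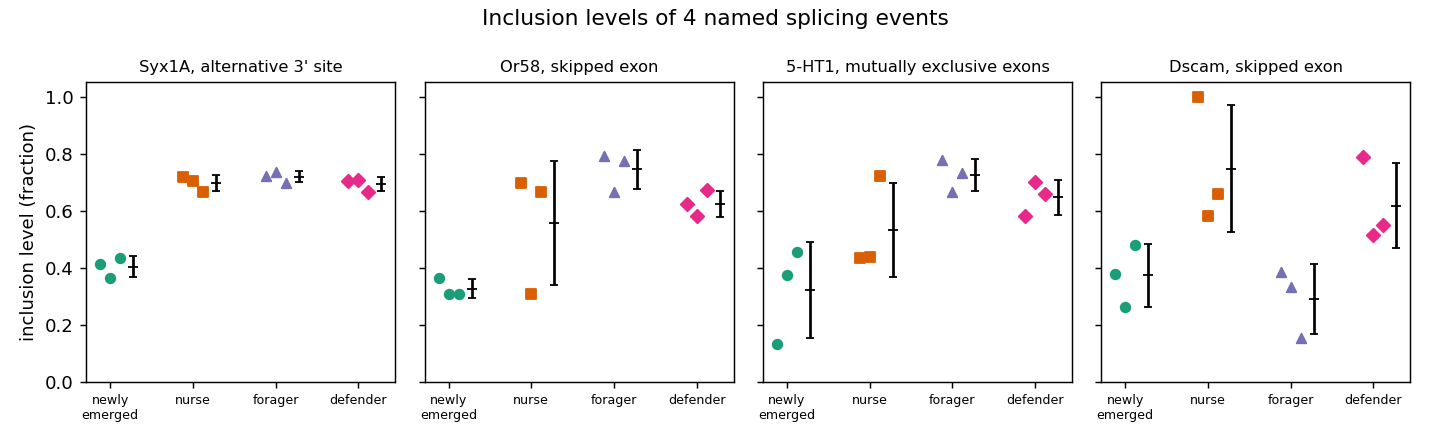
Inclusion level (0 to 1) of 4 splice events in the 4 worker groups, with points for libraries and mean ± SD. For Syx1A the newly emerged mean is 0.404 and the other 3 means lie between 0.693 and 0.719.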

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

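Leaving out libraries of groups outside a comparison, fits without the nurse group, other factors in the smaller fits, divided nurse libraries and list membership by looser matching were chosen after the results were seen; the other settings were planned. No call of a named gene reversed its direction under the settings run: of 2844 values, 2535 kept their side of the threshold and 309 no longer passed. Of 880 values of named genes without a call, 41 passed the threshold and 19 had the opposite sign. The excess of higher or lower calls turned in 1 setting for nurse against newly emerged, 4 for forager against nurse, 8 for defender against nurse, 8 for forager against newly emerged and 2 for defender against newly emerged, so the excess is no stable result; upper-quartile factors turned the first 4 of these. Of 1344 list counts, 1101 stayed within 1.5 times the reported count and 243 moved. None of 144 values of named splice events changed sign when 1 library was left out. Their size was also held against the spread between replicates. Leaving out 1 of 3 libraries cannot move a mean that far, so this limit shows nothing about how stable the values are. The splicing alternatives that need junction reads or an adjusted p per event were not run, since those values are not in the tables used here. In simulated data edgeR recovered 44.8% of genes changed 1.5-fold, so smaller changes can be missed at this number of libraries.

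With an absolute log2 fold change of at least 1, by construction a part of the calls, the counts were 1319 (nurse against newly emerged), 171 (forager against nurse), 216 (defender against nurse), 1805 (forager against newly emerged) and 1397 (defender against newly emerged). At an adjusted p under 0.01, a stricter threshold, they were 2743, 129 and 89 for the first 3 of these, 2542 for defenders against newly emerged workers and 3383 for the 4 groups together. The strict low-count filter, which tests fewer genes, gave 292 for forager against nurse, 2579 for defender against newly emerged and 226 for genes shared between the comparisons without a common library. DESeq2 gave 885 for forager against nurse, 1841 for defender against nurse and 1273 for defender against forager. It gave 614 shared genes without and 483 with common nurse libraries. The cause was not tested. In the simulated data DESeq2 made 35 false calls among 210, and edgeR 11 among 170. Fits of only the 2 groups gave 111 for forager against nurse, 431 for defender against nurse and 876 for defender against forager. The number term gave 1466 for defender against nurse, where libraries of 1 number were not positively correlated throughout, and 667 for defender against forager. Without the nurse group the latter was 1246 with the term and 975 without it. With RLE factors it was 869 (2 groups), 639 (number term) and 921 (without nurses), and with upper-quartile factors 807, 723 and 986. With nurse libraries divided, the genes shared by the comparisons with nurses were 20, 51 and 133 (nurse library 1, 2 or 3 alone for defenders) and 35, 54 and 59 (for foragers), with fewer controls per comparison. With an inclusion difference of at least 0.2, a further condition on the events, 57, 32 and 23 events remained for forager against nurse, defender against nurse and defender against forager.

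With each library left out in turn, the counts ran from 3262 to 4983 for nurse against newly emerged, 176 to 532 for forager against nurse and 99 to 1428 for defender against nurse. They ran from 0 to 1161 for defender against forager, 4287 to 5692 for forager against newly emerged, 3090 to 4299 for defender against newly emerged and 4319 to 5744 for the 4 groups together. The lowest value for forager against nurse came without nurse library 2, the lowest for defender against nurse without defender library 3 and the highest without nurse library 1, and the highest for defender against forager without nurse library 3; the cause was not tested.

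The opposite signs were all of genes without a call, at adjusted p of 0.665 or more. With upper-quartile factors Eaat-2 was at 0.0075 and Per at 0.099 for nurse against newly emerged (log2 fold changes), and Per at 0.014 for forager against newly emerged. Per was at 0.0033 for nurse against newly emerged with the strict low-count filter and Kr-h1 at 0.0059 for defender against forager with the number term. With libraries left out, values for nurse against newly emerged ran from -0.22 to 0.059 (Eaat-2) and -0.14 to 0.064 (Per). For forager against nurse they ran from -0.037 to 0.15 (Or11), -0.10 to 0.46 (Or2) and -0.22 to 0.012 (Per), and for defender against nurse from -0.11 to 0.038 (RpL32). For defender against forager they ran from -0.10 to 0.0027 (Eaat-2), -0.29 to 0.063 (GstD1), -0.16 to 0.20 (Kr-h1) and -0.62 to 0.13 (Melt).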

Other observations

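All tests of explanations in this part, and the unnamed genes below, were chosen after the results were seen. Among genes with only a LOC identifier, some changed in steps from newly emerged workers through nurses to foragers. LOC552811 was at 7.31 ± 0.988 CPM in newly emerged workers (SD, n = 3), 44.0 ± 17.2 in nurses, 458 ± 99.6 in foragers and 433 ± 34.1 in defenders. It rose in nurses (log2 fold change 2.59, SE 0.27, adjusted p = 2.6e-05) and again in foragers (log2 fold change 3.38, SE 0.28, adjusted p = 0.00012). LOC102656690 was at 0.0940 ± 0.0471, 2.54 ± 0.322, 6.52 ± 1.26 and 6.22 ± 1.33 CPM in the same order. LOC107965367 fell from 1859 ± 505 CPM in newly emerged workers to 3.80 ± 1.43 in nurses (log2 fold change -8.94, SE 0.43, adjusted p = 1e-07), and was at 0.696 ± 0.306 in foragers and 1.29 ± 0.443 in defenders. LOC552685 was at 425 ± 166, 10.1 ± 6.77, 0.120 ± 0.0439 and 0.177 ± 0.137 CPM in the same order. For LOC552811 and LOC552685 the difference between defenders and foragers had adjusted p = 0.878 and 0.696.

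Several genes of the amine list differed between newly emerged workers and foragers or defenders, while the list as a set did not pass. The serotonin receptor gene 5-ht7 fell from 8.90 ± 2.44 CPM in newly emerged workers to 1.51 ± 0.474 in foragers (log2 fold change -2.55, SE 0.38, adjusted p = 0.000203). Dop3 fell to 1.22 ± 0.441 CPM in foragers and 0.996 ± 0.0425 in defenders from 5.29 ± 0.898 in newly emerged workers (adjusted p = 0.000175 and 7.99e-05). 5-HT1 rose to 14.0 ± 2.56 and 12.5 ± 1.37 CPM from 3.93 ± 0.207 (adjusted p = 5.06e-06 and 1.14e-05). Of 8 genes in the amine list, 1 rose and 4 fell in foragers and 1 rose and 5 fell in defenders against newly emerged workers (1 and 5 in each adjusted over the list alone), and camera gave adjusted p = 0.122 and 0.0629 (adjusted p = 0.337 and 0.216 with an estimated correlation). Over all tested genes 47.9% and 34.4% were called in these comparisons.

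Mrjp1 to Mrjp5 transcripts varied together between the nurse libraries, while Mrjp8, Mrjp9 and Hbg3 varied less. The median SD over the 3 nurse libraries of the log2 ratios of Mrjp2 to Mrjp5 to Mrjp1 was 0.366, while log2 Mrjp1 itself had an SD of 1.67. That is what RNA of head glands carried into the libraries would give, and it may be the source, but genes of the antenna that are switched on together would give the same ratio. In nurse libraries 1, 2 and 3, where Mrjp1 was at 1236, 238 and 132 CPM, Mrjp9 was at 295, 276 and 257, Mrjp8 at 51.2, 25.2 and 34.8 and Hbg3 at 130.2, 106 and 97.7 CPM, and the test does not cover these. A single carried-over tissue that brought both these transcripts and those of Hex70a, Hex110 and Vg stays open. In the nurse library with most Mrjp1 (2.8 log2 units above the others) the 3 genes were lower, by a mean log2 difference of -2.05 (SD over the genes 0.189), but between the other 2 nurse libraries they were higher where Mrjp1 was, by 0.964 (SD over the genes 0.555), so 1 library decides. Nurse reads assigned to forager and defender libraries are argued against, since the ratio of Mrjp3 to Mrjp1 was at most 0.174 in the 5 such libraries with at least 5 CPM of Mrjp1 and at least 0.441 in nurses.

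The number of genes called between defenders and foragers depended on the fit. With all 12 libraries it was 0 (2705 genes at unadjusted p under 0.05, 1273 calls with DESeq2). The smallest adjusted p was then 0.0544, just above the threshold, so a small change of the fit can alter the number. It was 975 when the nurse group was left out, so the spread of the nurse libraries in the shared fit may account for the lack of calls. With the number term in the fit of all groups it was 667, so differences shared by libraries of 1 number may also add to it. Scaling is argued against, since with RLE or upper-quartile factors the fit of all libraries still made 0 calls and the fit without nurses at least 921. A difference between the tasks is the biological explanation that the design names, and it stays open. Age, which is not given, could not be told apart from it.

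Or2 fell in nurses against newly emerged workers while most other listed odorant receptor genes rose. A larger share of olfactory neuron RNA in nurse antennae would raise the receptors, Or2 and neuron markers together. Since Or2 fell, such a share alone would not give the whole pattern. For the receptors that rose it stays open, provided that Or2 fell for a separate reason. The median log2 fold change of the 6 neuron and synapse markers was 0.181 (SD 0.329) and that of the receptors other than Or2 0.518. The markers lay below the receptors by more than their SD with all libraries, but in only 3 of 6 fits with 1 library left out. That Or2 differs with age or task apart from the receptors was not tested.

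The 6 libraries of 2 groups can be divided in 10 ways, too few for a share under 0.05. Only 1 of the 10, the real one, gave as many genes for nurse against newly emerged (4460), forager against nurse (452), defender against nurse (872), forager against newly emerged (5403) and defender against newly emerged (3880), and the highest other was 0 in each. For defender against forager all 10 gave 0, the real value. Of 100 divisions of the 12 libraries into 4 groups of 3, only the real 1 gave 5472 genes or more, and the highest other gave 3075. This argues against a chance division of the 12 libraries as a whole. Newly emerged workers were the highest or lowest group for 87.2% of the 5472 genes, so divisions that mix their libraries can lose calls for that reason alone. The test thus does not decide how nurses, foragers and defenders divide.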
